A study of Mus musculus with 30 samples.

How the data were processed

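The series holds bulk RNA sequencing of T cell populations sorted by flow cytometry from mouse thymus and spleen, from control mice and mice with a conditional Prmt5 knockout. Libraries were poly(A)-selected and made with a strand-marking kit, per the labels' protocols. The values analysed are raw read counts per gene, deposited by the authors in 3 tables: thymus DP with thymus CD4 SP, thymus CD8 SP, and both spleen populations. HISAT2, HTSeq and the genome build GRCm38 are named per the submitters' processing notes. Their versions, the annotation and the strand setting of the counting are not given in the sources used here. Counts of a gene and of an antisense partner therefore cannot be told apart with certainty. The tables list 21983 gene symbols (thymus DP and CD4 SP) or 46095 (the others), so levels were tested only within a table. Only the lists of calls were compared across tables, over genes tested in both populations.

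Groups, replicate numbers and animals were taken from the sample titles. Each population was tested on its own 6 libraries, 3 mice per genotype, with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with its defaults, libraries scaled with TMM, and CKO compared with WT by the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05 and no fold threshold. Differences of genotype effects between populations of the same mice were tested as an interaction over 12 libraries. Gene lists, 24 in number, were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, two-sided, over lists with at least 5 measured members. No list passed in any comparison with an estimated correlation. The rotation test fry, which asks whether a list's genes move 1 way on balance, called 0 lists in each thymus comparison, 4 in spleen CD4 and 14 in spleen CD8. Shared calls were compared with Fisher's exact test over 10 pairs of comparisons and 2 directions. An SE is the fitted log2 fold change divided by the square root of its F statistic.

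The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Prmt5, the 8 genes with the largest fold in each direction among called genes with at least 5 CPM in the higher group and no overlap between the genotypes, 15 genes in every comparison, and 2 to 4 members with the smallest p of each list described; contrasts take 5 genes per side. Unnamed gene models, LOC symbols, symbols ending in -ps and variable or joining segments of receptors were left out by symbol, so the annotated pseudogene Gbp11 and the Tcrg symbols remained. Some genes that the rule names are not reported here. In the thymus these genes are given in part, with others in the plot of log2 fold changes.

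Total counts per library ran from 11865646 to 35353441; 10 counts in the shallowest library equal 0.843 CPM. Intervals from counts cover counting error only. The test was tried on simulated counts for the same libraries with 200 changed genes: of genes changed by a log2 of 1, 93% were recovered in thymus DP, 2% in thymus CD4 SP, 86% in thymus CD8 SP, 83% in spleen CD4 and 81% in spleen CD8. Of the calls 7.25% were false in thymus DP and 7.02% in the spleen contrast (6.88% with the animal as a block). The share was 5.70% in spleen CD4, 5.29% in spleen CD8 and 5.10% in thymus CD8 SP. All these lay above the nominal rate, while thymus CD4 SP had 0% and the thymus contrast 3.23%. Each simulated gene had the same spread in every library, independent of other genes.

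Alternatives were DESeq2 1.42.0, its size factors in edgeR, limma voom with quality weights, no filter, a filter of 5 CPM in 3 libraries, each library left out, all 12 libraries of a table in the fit, and the replicate number or animal as a block. Thymus DP with CD4 SP and spleen CD4 with CD8 are paired by animal, per the labels. Correlations of deviations across genes were 0.0989 to 0.317 for the same animal in the spleen, against -0.187 to 0.0109 for different animals. In the thymus 5 of the 6 animals had positive values, and CKO 23 went against the labels, at -0.135 with itself and 0.168 between its DP library and CD4 SP of CKO 14. WT and CKO libraries of thymus CD8 SP with the same number had 0.0529 to 0.127, against -0.0974 to 0.00645 for other numbers. What these numbers link is not stated, and they served as a block only in an alternative. Sex is not in the labels and was read from Xist and Ddx3y. By Ddx3y (155 to 210 CPM), WT 18 and CKO 17 were male in thymus DP and CD4 SP. Ddx3y was 0 CPM in both CKO 14 libraries and 3.76 and 9.10 CPM in those of CKO 23, which goes with their labels. No library pair within a group agreed within sampling noise.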

Results

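RNA was sequenced from sorted T cells of control mice (WT) and of mice with a conditional knockout of Prmt5 (CKO), the gene of an arginine methyltransferase that places symmetric dimethyl marks on histones, splicing proteins and other substrates. By the labels, CKO mice carried CD4-Cre with floxed Prmt5, and WT mice were wild type. No group is labelled as CD4-Cre alone, so effects of Cre and of Prmt5 loss cannot be told apart. The 30 libraries covered 5 populations, with 3 mice per genotype in each. From the thymus these were double-positive cells (DP, which carry both CD4 and CD8), CD4 single-positive cells (CD4 SP) and CD8 single-positive cells (CD8 SP). From the spleen they were CD4 and CD8 cells. Total gene counts per library ran from 13032992 to 18576401 in thymus DP, 11865646 to 22881226 in thymus CD4 SP, 28721963 to 35353441 in thymus CD8 SP, 24729146 to 27137018 in spleen CD4 and 25426449 to 27192847 in spleen CD8. Animal numbers in the labels link thymus DP with thymus CD4 SP, and spleen CD4 with spleen CD8. Log2 fold changes are CKO over WT with their standard error (SE), CPM values are means ± SD over 3 libraries, and adjusted p-values come from edgeR's quasi-likelihood test unless a gene list is named.

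The targeted transcript was lower in CKO in every population, by different amounts. Part of it remained in each, and whether this came from cells that kept the gene was not tested. Prmt5 (chromosome 14, 54507187 to 54517525, GRCm38) went from 65.3 ± 5.06 to 30.6 ± 0.497 CPM in thymus DP (log2 -1.09 ± 0.09, adjusted p = 8.45e-04). In spleen CD4 it fell from 44.3 ± 0.572 to 22.5 ± 2.86 CPM (log2 -0.97 ± 0.10, adjusted p = 1.09e-04), and in spleen CD8 from 64.4 ± 3.07 to 35.1 ± 6.18 CPM (log2 -0.87 ± 0.12, adjusted p = 8.29e-04). Thymus CD4 SP had a decrease of similar size, from 62.3 ± 5.38 to 31.4 ± 10.9 CPM, that did not pass the test (log2 -0.99 ± 0.27, adjusted p = 0.958). In thymus CD8 SP the change was smaller, from 144 ± 7.90 to 116 ± 1.52 CPM (log2 -0.31 ± 0.05, adjusted p = 0.0450). All 3 CKO libraries lay below all 3 WT libraries in each population, where 10% of genes would show no overlap by chance in a population. The thymus CD8 SP call was lost when any 1 of the 6 libraries was left out, with adjusted p from 0.0541 to 0.164. The thymus DP call was lost in a fit over the 12 libraries of its table (adjusted p = 1).

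**Figure D1:**
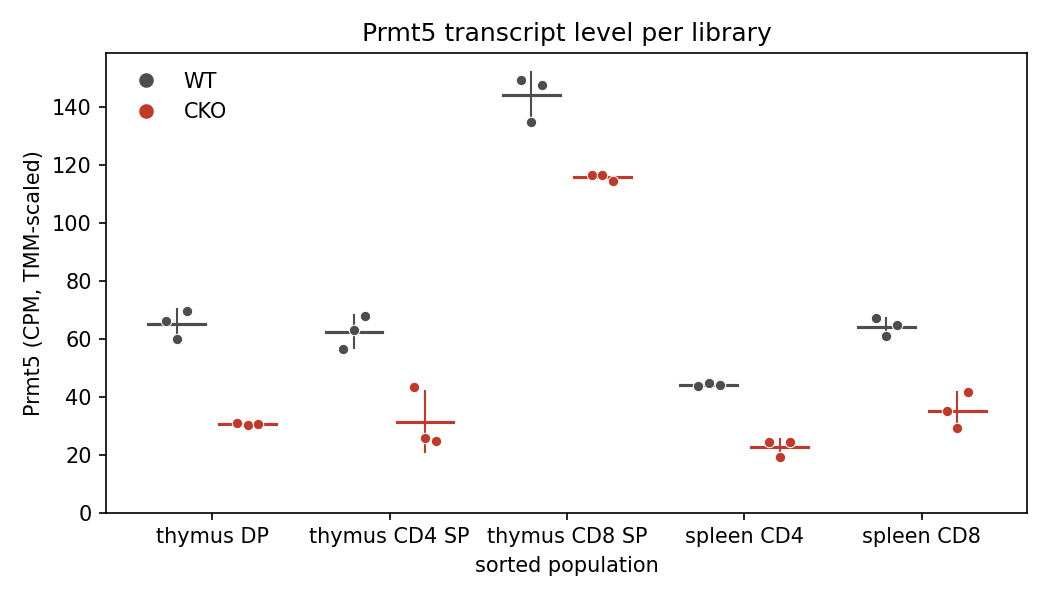
Prmt5 level in CPM (TMM-scaled) in each of the 30 libraries, by population on the horizontal axis, with WT in grey and CKO in red. Horizontal lines are group means and vertical lines ± 1 SD over 3 libraries; thymus CD8 SP shows the smallest log2 fold change, -0.31 ± 0.05.

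The comparison in thymus DP asks what Prmt5 loss does at the stage where both coreceptors are present. Bmf, a pro-apoptotic BH3-only gene, rose from 192 ± 10.6 to 291 ± 11.5 CPM (log2 0.60 ± 0.07, adjusted p = 0.00823). Mbnl1, which encodes a splicing regulator, rose from 466 ± 17.3 to 684 ± 6.23 CPM (log2 0.56 ± 0.06, adjusted p = 0.00823). Mbnl1 (chromosome 3, 60472830 to 60629750) lies within 1 Mb of Gm33707 (from 60769887), a gene model present almost only in CKO libraries of other populations. Its rise can therefore not be assigned to Prmt5 loss alone. The coreceptor genes Cd4 (log2 0.01 ± 0.07, adjusted p = 0.985) and Cd8a (log2 0.04 ± 0.07, adjusted p = 0.943) gave no call. Of 11634 genes tested 2 were higher and 1, Prmt5, lower, with 822 at an unadjusted p under 0.05 where 582 would be reached by chance. DESeq2 called 6 higher and 8 lower. The calls of Bmf and Mbnl1 were lost without WT 18, without WT 24 or without CKO 14 (0 genes higher each). Both were also lost in the fit over the 12 libraries of the table. Leaving out WT 15 gave 38 genes lower and leaving out CKO 23 gave 7 higher and 2 lower.

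Cell cycle genes formed the group with the most uniform direction in thymus DP. For this list 0 of the 39 measured members were higher, 0 lower and 39 did not pass; 0 were higher and 9 lower adjusted over the list alone; all 39 estimates were negative (adjusted p = 1.34e-20 with the preset correlation and adjusted p = 0.337 with an estimated correlation). Examples were Cenpf (log2 -0.55 ± 0.11, adjusted p = 0.660) and Kif23 (log2 -0.44 ± 0.10, adjusted p = 0.660), which act in mitosis and did not pass over all genes. DESeq2 called both lower (Cenpf adjusted p = 0.00390, Kif23 0.0294), with Cenpe (0.0428). The fit without WT 15 called Cenpf (0.0163), Kif23 and Cenpe (0.0420 each) and Cdc20 (0.0180) lower, and the fit with no filter called Cenpf (0.0253). In the list of mature single-positive thymocyte genes 0 of the 24 measured members were higher, 0 lower and 24 did not pass. Itm2a stood at 0.41 ± 0.09 and Gimap6 at 0.33 ± 0.10, and adjusted over the list alone 1 was higher and 0 lower (adjusted p = 0.00318 with the preset correlation and adjusted p = 0.369 with an estimated correlation). In the T cell receptor list 0 of the 25 measured members were higher, 0 lower and 25 did not pass. Cd2 stood at 0.41 ± 0.13 and Nfatc1 at 0.18 ± 0.07, and adjusted over the list alone 0 were higher and 0 lower (adjusted p = 2.61e-04 with the preset correlation and adjusted p = 0.337 with an estimated correlation). In the immediate early and heat shock list 0 of the 17 measured members were higher, 0 lower and 17 did not pass. Dusp2 stood at -0.29 ± 0.11 and Dnajb1 at -0.13 ± 0.06, and adjusted over the list alone 0 were higher and 0 lower (adjusted p = 0.0301 with the preset correlation and adjusted p = 0.369 with an estimated correlation). The mature list lost its call without WT 18 or CKO 23. The heat shock list lost it without WT 24 or CKO 17.

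In thymus CD4 SP, where the question was what Prmt5 loss changes once the CD4 lineage is chosen, no gene passed the threshold. The largest estimate among the genes named in every comparison was that of Gzmb, a cytotoxic granule protease, with 4.78 ± 1.05 to 0.117 ± 0.112 CPM (log2 -5.45 ± 0.61, adjusted p = 0.538). The lymph node homing gene Ccr7 had a positive estimate (log2 0.78 ± 0.34, adjusted p = 0.958). edgeR called 0 of 11839 genes, with 306 at an unadjusted p under 0.05 against 592 by chance; DESeq2 called 1 gene lower, Gzmb (log2 -5.57, adjusted p = 5.72e-09), and limma voom 0. The Gzmb estimate was -6.36 without CKO 23. In simulated data, 2% of genes changed by a log2 of 1 were recovered and 57% of those changed by 2. Most smaller differences would be missed in such data. Each simulated gene had the same spread in all 6 libraries, independent of other genes. The real spread lay mainly in CKO 14 and CKO 17, so the share missed in the real data can differ.

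Thymus CD4 SP libraries of both genotypes carried markers of the DP stage. The 3 CKO libraries differed from each other in these markers. Cd8a stood at 2424 CPM in CKO 14, 43.3 in CKO 17 and 947 in CKO 23, against 1086 to 1532 in WT. Rag1, a recombination gene of the DP stage, stood at 2096, 30.2 and 947 CPM, against 700 to 1759 in WT. Thymus DP libraries had 2608 to 2825 CPM of Cd8a and 2805 to 4011 CPM of Rag1. CKO 17 carried the least of this signal. Its DP list had a mean log2 CPM of 5.06, against 7.18 to 7.57 in the rest. What share of the sorted cells had chosen the CD4 lineage was not tested. Beside these differences, in the mature single-positive list 0 of the 24 measured members were higher, 0 lower and 24 did not pass. Cd52 stood at 0.93 ± 0.26 and Klf2 at 0.82 ± 0.27, and adjusted over the list alone 0 were higher and 0 lower (adjusted p = 1.02e-07 with the preset correlation and adjusted p = 0.429 with an estimated correlation). In the double-positive list 0 of the 18 measured members were higher, 0 lower and 18 did not pass. Mns1 stood at -1.24 ± 0.44 and Ccr9 at -0.55 ± 0.29, and adjusted over the list alone 0 were higher and 0 lower (adjusted p = 2.19e-04 with the preset correlation and adjusted p = 0.456 with an estimated correlation). In the cell cycle list 0 of the 39 measured members were higher, 0 lower and 39 did not pass; 0 were higher and 0 lower adjusted over the list alone, and its signs differed, with a median of 0.03, a mean of -0.12 and a test pointing down (adjusted p = 0.00168 with the preset correlation and adjusted p = 0.522 with an estimated correlation), with Bub1 at -1.12 ± 0.32 and Cenpf at -1.36 ± 0.49. In the interferon list 0 of the 34 measured members were higher, 0 lower and 34 did not pass. Isg20 stood at 0.73 ± 0.25 and Ifi27l2a at 0.71 ± 0.33, and adjusted over the list alone 0 were higher and 0 lower (adjusted p = 0.00450 with the preset correlation and adjusted p = 0.583 with an estimated correlation). The last pair of lists turned direction without CKO 17, with adjusted p = 0.524 and 0.350.

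Further lists in thymus CD4 SP were called with the preset correlation, some of them led by members at low levels. In the effector list 0 of the 29 measured members were higher, 0 lower and 29 did not pass. Nkg7 stood at -1.12 ± 0.31 and Ifng at -3.22 ± 1.11, and adjusted over the list alone 0 were higher and 1 lower (adjusted p = 0.00646 with the preset correlation and adjusted p = 0.429 with an estimated correlation). In the regulatory and helper list 0 of the 15 measured members were higher, 0 lower and 15 did not pass. Foxp3 stood at 1.33 ± 0.47 and Gpr83 at 0.99 ± 0.34, and adjusted over the list alone 0 were higher and 0 lower (adjusted p = 0.00485 with the preset correlation and adjusted p = 0.429 with an estimated correlation). In the T cell receptor list 0 of the 25 measured members were higher, 0 lower and 25 did not pass. Cd2 stood at 0.84 ± 0.26 and Ptpn6 at 0.64 ± 0.32, and adjusted over the list alone 0 were higher and 0 lower (adjusted p = 0.00168 with the preset correlation and adjusted p = 0.429 with an estimated correlation). Among myeloid markers 0 of the 17 measured members were higher, 0 lower and 17 did not pass. C1qa stood at 0.84 ± 0.33 and C1qc at 1.08 ± 0.45, and adjusted over the list alone 0 were higher and 0 lower (adjusted p = 0.0149 with the preset correlation and adjusted p = 0.456 with an estimated correlation). The effector list and the myeloid list lost their calls without CKO 14 or CKO 23. The interferon list lost it without WT 24 or CKO 17, the regulatory and helper list without WT 24, CKO 17 or CKO 23, and the cell cycle and double-positive lists without CKO 17. Without CKO 17 the estimate of Foxp3 was 0.59, and without CKO 23 that of Ifng was -7.25.

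The same question was asked for the CD8 lineage, but how far these cells had chosen it was not tested. Rag1 stood at 709 to 899 CPM in thymus CD8 SP libraries, against 2805 to 4011 in thymus DP. Mki67, a marker of dividing cells, stood at 2161 to 2559 CPM, against 915 to 1484 in thymus DP. Thymus DP is in another table, so these levels were not tested against each other. Thymus CD8 SP cells had lower levels of several interferon-induced genes in CKO. Oas3, a sensor of double-stranded RNA, fell from 51.7 ± 0.507 to 35.9 ± 3.40 CPM (log2 -0.53 ± 0.07, adjusted p = 0.0292). Oas2 (log2 -0.53 ± 0.08, adjusted p = 0.0450), of the same family, and Irf7 (log2 -0.59 ± 0.09, adjusted p = 0.0315), an interferon regulatory factor, were lower as well. In the interferon list 0 of the 35 measured members were higher, 4 lower and 31 did not pass; 0 were higher and 25 lower adjusted over the list alone; all 35 estimates were negative (adjusted p = 1.45e-26 with the preset correlation and adjusted p = 0.206 with an estimated correlation). Further genes that passed and were lower were Tmie (-0.71 ± 0.10), the Notch regulator Dtx1 (-0.60 ± 0.08), Btbd11 (-0.58 ± 0.07), Tspan9 (-0.58 ± 0.09) and Ifi203 (-0.45 ± 0.07). Higher genes were the kinesin Kifc1 (log2 2.67 ± 0.42, adjusted p = 0.0450), Pdlim4 (0.76 ± 0.10), Tubb3 (0.60 ± 0.09) and Mbnl1 (log2 0.25 ± 0.04, adjusted p = 0.0315). Gm33707, the neighbour of Mbnl1, was higher in the same libraries (log2 7.35 ± 0.59).

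Of 14911 genes tested in thymus CD8 SP 5 were higher and 12 lower, with 1548 at an unadjusted p under 0.05 against 746 by chance; DESeq2 called 79 higher and 126 lower. Among the latter were Btg1 (adjusted p = 7.94e-05), Ccr7 (1.10e-04), Klf2 (4.92e-04), Il4ra (0.0101) and Gimap6 (0.0142), and among the former Cd4 (0.00339) and Dgkeos (0.0347), none of which passed with edgeR. Btg1 also passed with limma voom (0.0489). All 7 passed with no filter as well, and Ccr7 passed without CKO 3. By Xist and Ddx3y, all 3 WT libraries and CKO 1 came from male mice (Xist 3.77 to 5.28 CPM) and CKO 2 and CKO 3 from female mice (Xist 2152 and 1923 CPM). With sex as a covariate 2 genes were higher and 1 lower, and of 13 called genes named besides Prmt5 12 lost the call, Oas3 among them. In that fit the genotype effect rests on CKO 1 alone, the only male CKO library. The 13 estimates kept their direction, with Oas3 at -0.57 against -0.53 without the covariate, so the lost calls do not show sex to be the source. Kifc1 also lost its call with limma voom and with the strict filter. Without WT 2 or without WT 3 the counts were 1 higher and 0 lower, and without WT 1 they were 8 and 40. Without CKO 1 they were 11 and 19, and without CKO 2 or CKO 3 they were 2 and 5 or 3 and 9.

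Other lists were called in thymus CD8 SP with the preset correlation, mostly through members that did not pass. In the mature single-positive list 0 of the 24 measured members were higher, 0 lower and 24 did not pass. Ccr7 stood at -0.38 ± 0.08 and Klf2 at -0.36 ± 0.07, and adjusted over the list alone 0 were higher and 8 lower (adjusted p = 2.03e-08 with the preset correlation and adjusted p = 0.281 with an estimated correlation). In the double-positive list 0 of the 19 measured members were higher, 0 lower and 19 did not pass. Rag2 stood at 0.28 ± 0.07 and Dgkeos at 0.29 ± 0.08, and adjusted over the list alone 5 were higher and 1 lower (adjusted p = 3.95e-04 with the preset correlation and adjusted p = 0.323 with an estimated correlation). In the cell cycle list 0 of the 40 measured members were higher, 0 lower and 40 did not pass. Mki67 stood at 0.13 ± 0.04 and Cdca3 at 0.14 ± 0.04, and adjusted over the list alone 0 were higher and 0 lower (adjusted p = 7.47e-10 with the preset correlation and adjusted p = 0.281 with an estimated correlation). In the ribosome biogenesis list 0 of the 26 measured members were higher, 0 lower and 26 did not pass. Cirh1a stood at -0.20 ± 0.06 and Polr1a at -0.17 ± 0.05, and adjusted over the list alone 0 were higher and 0 lower (adjusted p = 1.89e-10 with the preset correlation and adjusted p = 0.281 with an estimated correlation). For cholesterol biosynthesis 0 of the 20 measured members were higher, 0 lower and 20 did not pass. Fdft1 stood at 0.22 ± 0.07 and Hmgcs1 at 0.20 ± 0.06, and adjusted over the list alone 1 was higher and 0 lower (adjusted p = 7.85e-05 with the preset correlation and adjusted p = 0.323 with an estimated correlation). Gzma (log2 0.04 ± 0.09, adjusted p = 0.932) and Cd8a (log2 0.03 ± 0.06, adjusted p = 0.914) did not pass.

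A further 4 lists had negative estimates on balance in thymus CD8 SP. In the immediate early and heat shock list 0 of the 18 measured members were higher, 0 lower and 18 did not pass. Btg1 stood at -0.26 ± 0.05 and Dnaja1 at -0.44 ± 0.09, and adjusted over the list alone 0 were higher and 6 lower (adjusted p = 1.60e-06 with the preset correlation and adjusted p = 0.323 with an estimated correlation). Of its 18 estimates 17 were negative. The chaperone gene Hsph1 went from 626 ± 185 to 339 ± 86.2 CPM and did not pass (log2 -0.89 ± 0.20, adjusted p = 0.131). In the naive and memory precursor list 0 of the 24 measured members were higher, 0 lower and 24 did not pass; 0 were higher and 5 lower adjusted over the list alone (adjusted p = 0.0187 with the preset correlation and adjusted p = 0.502 with an estimated correlation), with Ccr7 and Klf2 as above. In the common gamma chain cytokine list 0 of the 22 measured members were higher, 0 lower and 22 did not pass. Il4ra stood at -0.22 ± 0.05 and Il2rb at -0.21 ± 0.08, and adjusted over the list alone 0 were higher and 1 lower (adjusted p = 0.00888 with the preset correlation and adjusted p = 0.281 with an estimated correlation). In the arginine methyltransferase list 0 of the 11 measured members were higher, 1 lower and 10 did not pass; 0 were higher and 1 lower adjusted over the list alone (adjusted p = 0.00894 with the preset correlation and adjusted p = 0.362 with an estimated correlation), with Prmt5 itself, set by the design, and Riok1 (0.16 ± 0.06). Riok1 had the only positive estimate of the arginine methyltransferase list, and the other 10 were negative. The naive list lost its call without WT 2, WT 3 or CKO 2. The common gamma chain list lost it without CKO 2 and the arginine methyltransferase list without CKO 1.

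**Figure D2:**
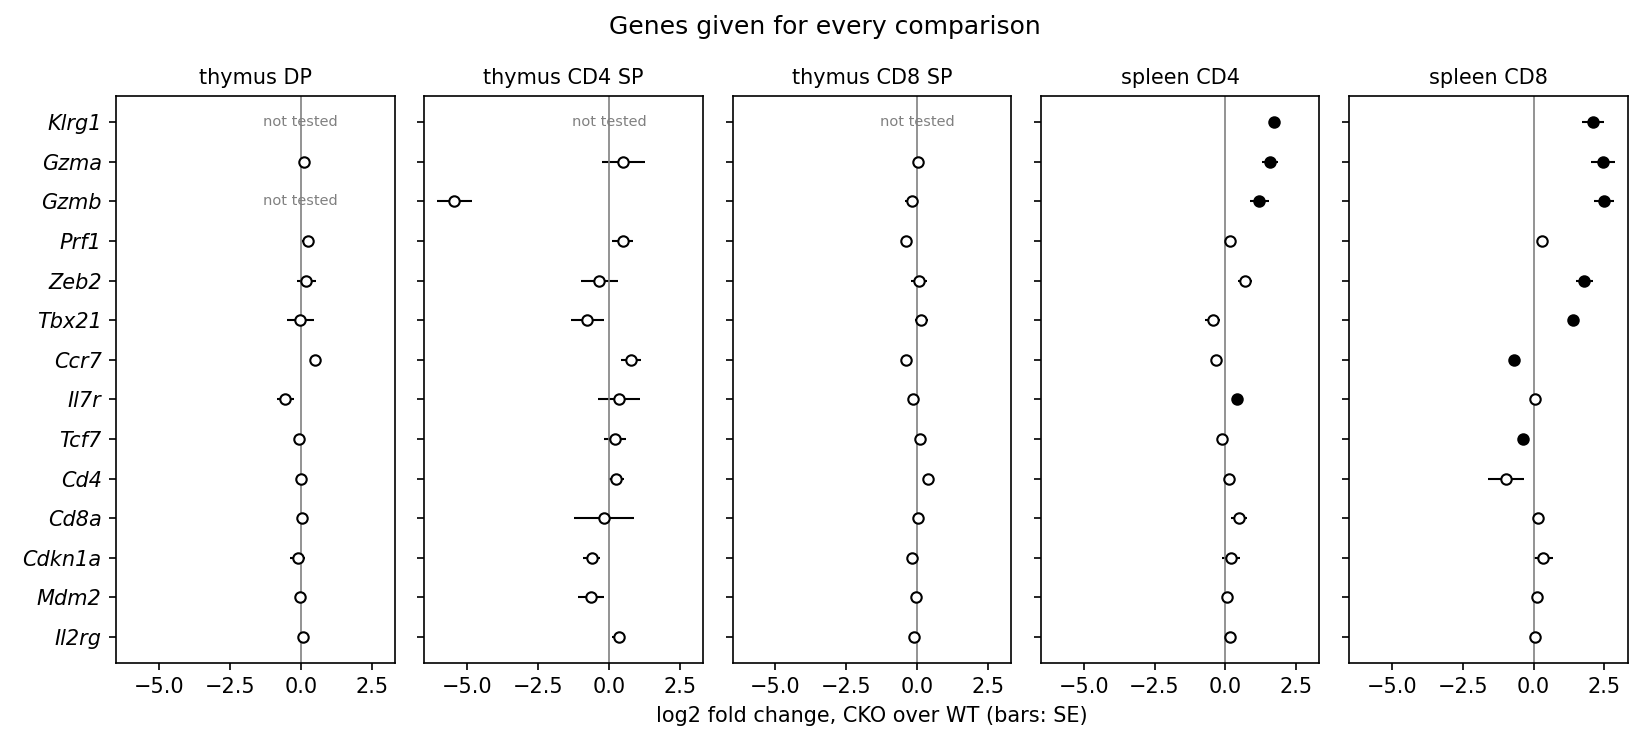
Log2 fold change, CKO over WT, of 14 genes given for every comparison, with 1 panel per population; bars are ± SE over 3 libraries per genotype, filled points have an adjusted p under 0.05 and genes below the count filter are marked as not tested. None of these genes passed in the thymus panels, while Klrg1 was at 1.72 ± 0.19 in spleen CD4 and 2.08 ± 0.39 in spleen CD8.

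In the spleen the question was which programmes of mature cells change in CKO mice, where part of the Prmt5 transcript remained. Spleen CD4 cells of CKO mice had far lower levels of some cytokine and helper genes. Il21, the cytokine of follicular helper cells (chromosome 3, 37222759 to 37232636), fell from 9.47 ± 7.35 to 0.384 ± 0.130 CPM, 24.1-fold lower (log2 -4.59 ± 0.59, adjusted p = 4.21e-04). Il10, an anti-inflammatory cytokine, was 9.24-fold lower (log2 -3.21 ± 0.29, adjusted p = 4.04e-05). The follicle homing receptor Cxcr5 went from 27.3 ± 8.25 to 8.03 ± 1.84 CPM (log2 -1.75 ± 0.21, adjusted p = 2.87e-04), and Ctla4, an inhibitory receptor of regulatory cells, from 104 ± 12.8 to 55.5 ± 2.41 CPM (log2 -0.90 ± 0.09, adjusted p = 5.82e-05). In the regulatory and helper list 0 of the 18 measured members were higher, 13 lower and 5 did not pass; 0 were higher and 13 lower adjusted over the list alone (adjusted p = 1.64e-09 with the preset correlation and adjusted p = 0.330 with an estimated correlation). In the inhibitory receptor list 1 of the 17 measured members were higher, 9 lower and 7 did not pass. Lag3 stood at -2.50 ± 0.28 and Tigit at -1.04 ± 0.15, and adjusted over the list alone 1 was higher and 11 lower (adjusted p = 4.63e-06 with the preset correlation and adjusted p = 0.330 with an estimated correlation). Other genes with large decreases were Sostdc1 (-4.49 ± 0.73), Angptl2 (-3.86 ± 0.37), the calcium channel gene Cacna1d (-3.64 ± 0.38), Gpm6b (-3.38 ± 0.29), Fam160a1 (-3.30 ± 0.32) and the activity-induced factor Npas4 (-3.17 ± 0.41). Some of these sizes rested on single libraries. Without WT 71 the estimate of Il21 was -3.79 and that of Sostdc1 -3.65, against -6.56 for Sostdc1 without CKO 68, and without CKO 65 that of Npas4 was -3.89.

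**Figure D3:**
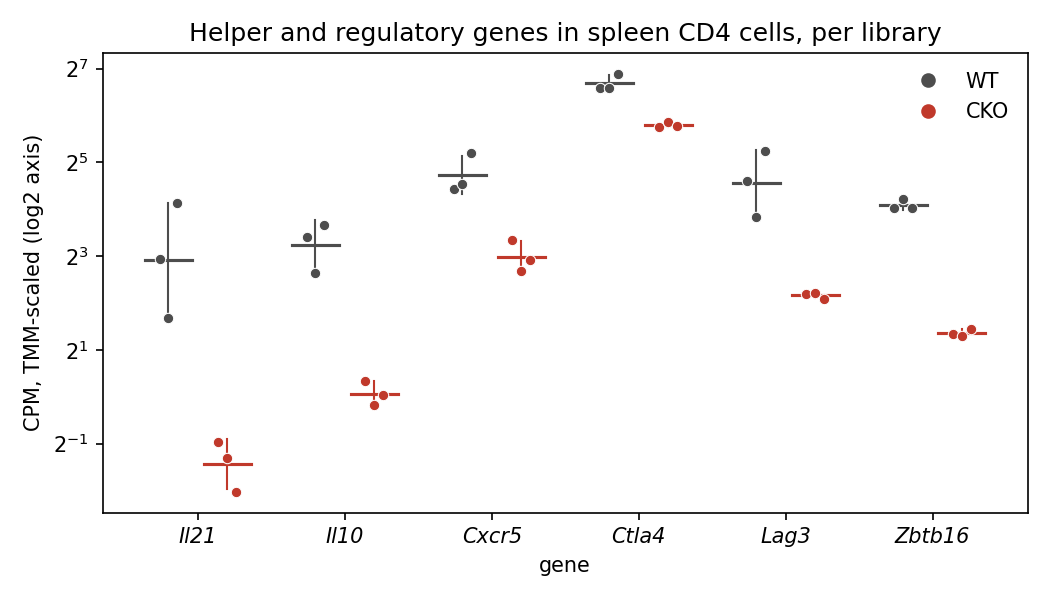
Levels of 6 helper, regulatory and innate-like genes in spleen CD4 cells per library, in CPM on a log2 axis, with WT in grey and CKO in red. Horizontal lines are means of log2 CPM and vertical lines ± 1 SD over 3 libraries; Il21 went from 9.47 ± 7.35 to 0.384 ± 0.130 CPM, and for each gene the CKO libraries lie below the WT libraries.

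Among the genes that rose in spleen CD4, Ggt1, a glutathione-cleaving enzyme, was 6.92-fold higher, from 9.35 ± 1.36 to 64.5 ± 5.25 CPM (log2 2.79 ± 0.11, adjusted p = 7.62e-08). Phlda3, a p53 target, was 4.37-fold higher (log2 2.13 ± 0.24, adjusted p = 1.92e-04), and Fcgrt, the neonatal Fc receptor, 4.40-fold (log2 2.14 ± 0.14, adjusted p = 5.63e-06). In the p53 target list 4 of the 26 measured members were higher, 3 lower and 19 did not pass. That list was not called (adjusted p = 0.205 with the preset correlation and adjusted p = 0.552 with an estimated correlation). Drc1 (2.67 ± 0.22), Mmp25 (2.32 ± 0.38), Unc13a (2.20 ± 0.33), Snrnp40 (2.15 ± 0.31) and Gbp11 (2.39 ± 0.17), annotated as a polymorphic pseudogene with uncertain counts, also rose. Without WT 70 the estimate of Mmp25 was 3.15. The terminal effector marker Klrg1 (chromosome 6, 122270596 to 122282882) rose from 7.10 ± 1.14 to 23.3 ± 5.93 CPM (log2 1.72 ± 0.19, adjusted p = 1.48e-04), with the granzymes Gzma (log2 1.58 ± 0.29, adjusted p = 0.00413) and Gzmb (log2 1.20 ± 0.34, adjusted p = 0.0329). Zeb2 (log2 0.69 ± 0.23, adjusted p = 0.0693), Tbx21 (log2 -0.45 ± 0.26, adjusted p = 0.289) and Prf1 (log2 0.17 ± 0.11, adjusted p = 0.355) did not pass. In the effector list 6 of the 38 measured members were higher, 2 lower and 30 did not pass; 10 were higher and 5 lower adjusted over the list alone (adjusted p = 0.210 with the preset correlation and adjusted p = 0.745 with an estimated correlation). The summed level of its 38 members was 2764 ± 114 CPM in WT and 2672 ± 546 CPM in CKO. Il7r, a gene of naive cells, rose (log2 0.41 ± 0.08, adjusted p = 0.00720), while Ccr7 (log2 -0.33 ± 0.10, adjusted p = 0.0574) and Tcf7 (log2 -0.12 ± 0.07, adjusted p = 0.306) did not pass. DESeq2 called Zeb2 higher (adjusted p = 0.0272) and Ccr7 lower (0.0124). Zeb2 also passed without CKO 68 and Ccr7 without WT 67, while Tbx21 was called lower without CKO 65. All 3 passed with no filter, and Il2rg passed in the fit over 12 libraries. Cd4, Cd8a, Cdkn1a, Mdm2 and Il2rg gave no call, with adjusted p from 0.0843 to 0.711.

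Some markers of other cell types changed as well in spleen CD4 of CKO mice. Whether such cells in the sort account for the rise of Klrg1, Gzma and Gzmb was not tested. The summed level of the myeloid and dendritic list was 160 ± 22.3 CPM in WT and 306 ± 92.8 CPM in CKO. CKO 72 had the highest of these sums (407 CPM), of Klrg1 (28.9) and of Gzma (16.5), while Gzmb was highest in CKO 65 (12.2). Among myeloid and dendritic markers 14 of the 17 measured members were higher, 0 lower and 3 did not pass; 15 were higher and 0 lower adjusted over the list alone (adjusted p = 7.14e-08 with the preset correlation and adjusted p = 0.437 with an estimated correlation); Itgam went from 8.76 ± 0.897 to 16.4 ± 2.70 CPM and Tyrobp from 2.21 ± 0.308 to 5.71 ± 1.97 CPM. Among natural killer markers 6 of the 10 measured members were higher, 1 lower and 3 did not pass. Ncr1 stood at 1.28 ± 0.31 and Klrb1c at -1.22 ± 0.18, and adjusted over the list alone 7 were higher and 1 lower (adjusted p = 0.0105 with the preset correlation and adjusted p = 0.330 with an estimated correlation). In the ribosome biogenesis list 0 of the 26 measured members were higher, 7 lower and 19 did not pass. Npm1 stood at -0.33 ± 0.06 and Ncl at -0.31 ± 0.08, and adjusted over the list alone 2 were higher and 15 lower (adjusted p = 0.00155 with the preset correlation and adjusted p = 0.546 with an estimated correlation). For cholesterol biosynthesis 0 of the 20 measured members were higher, 2 lower and 18 did not pass. Insig1 stood at -0.59 ± 0.08 and Srebf2 at -0.24 ± 0.07, and adjusted over the list alone 0 were higher and 1 lower (adjusted p = 0.00255 with the preset correlation and adjusted p = 0.546 with an estimated correlation). In the arginine methyltransferase list 0 of the 11 measured members were higher, 2 lower and 9 did not pass; 0 were higher and 2 lower adjusted over the list alone (adjusted p = 0.0171 with the preset correlation and adjusted p = 0.330 with an estimated correlation), with Prmt5 itself, set by the design, and Prmt3 (-0.39 ± 0.09).

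Of 14292 genes tested in spleen CD4 1219 were higher and 805 lower, 259 and 148 of them by at least 2-fold. The counts moved by over 1.5 times without WT 71 (706 higher, 379 lower) and without WT 70 (767 and 445), and the lower count without WT 67 (520) and without CKO 72 (522). The Gzmb call was lost without WT 70, WT 71, CKO 65 or CKO 72, and in the fit over all 12 libraries of the table. Srebf2 lost its call in 5 of the 6 fits that left out 1 library, all but the one without CKO 68. Ncl lost it without WT 70 or CKO 72, Il4 (-3.21 ± 0.73) without WT 70 or WT 71, and Prmt3 and Ncr1 without WT 71.

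Spleen CD8 cells of CKO mice had higher levels of effector genes. Klrg1 rose from 3.86 ± 2.57 to 16.3 ± 4.14 CPM, 4.23-fold (log2 2.08 ± 0.39, adjusted p = 0.00466), Gzma from 23.9 ± 13.3 to 129 ± 60.4 CPM (log2 2.44 ± 0.42, adjusted p = 0.00304) and Gzmb (chromosome 14, 56258838 to 56262260) from 14.8 ± 7.55 to 82.4 ± 31.8 CPM (log2 2.48 ± 0.37, adjusted p = 0.00128). The transcription factors of effector differentiation Zeb2 (log2 1.79 ± 0.31, adjusted p = 0.00296) and Tbx21 (log2 1.39 ± 0.15, adjusted p = 2.87e-04) rose as well. In the effector and cytotoxic list 35 of the 38 measured members were higher, 0 lower and 3 did not pass. Lgals1 stood at 1.49 ± 0.11, Ahnak at 1.16 ± 0.08 and S100a6 at 2.26 ± 0.17, and adjusted over the list alone 36 were higher and 0 lower (adjusted p = 2.46e-26 with the preset correlation and adjusted p = 0.146 with an estimated correlation). Prf1, the pore-forming perforin, did not pass (log2 0.29 ± 0.14, adjusted p = 0.199). Prf1 passed without CKO 68 and with no filter. Without WT 70 the estimate of Klrg1 was 2.71.

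In the list of naive and memory precursor genes 3 of the 24 measured members were higher, 9 lower and 12 did not pass; 4 were higher and 14 lower adjusted over the list alone (adjusted p = 0.00212 with the preset correlation and adjusted p = 0.146 with an estimated correlation). Ccr7 fell from 719 ± 86.2 to 442 ± 77.6 CPM (log2 -0.69 ± 0.12, adjusted p = 0.00304), and Tcf7, a factor of naive and memory cells, from 1238 ± 63.2 to 945 ± 89.4 CPM (log2 -0.38 ± 0.08, adjusted p = 0.00712). S1pr1 (-0.62 ± 0.08) and Lef1 (-0.45 ± 0.07) were lower too. Il7r (log2 0.04 ± 0.07, adjusted p = 0.789), Cd8a (log2 0.14 ± 0.09, adjusted p = 0.327), Cdkn1a (log2 0.35 ± 0.33, adjusted p = 0.535), Mdm2 (log2 0.13 ± 0.10, adjusted p = 0.401) and Il2rg (log2 0.05 ± 0.06, adjusted p = 0.625) did not pass. Mdm2 passed without CKO 65. Cd4 did not pass either (log2 -0.98 ± 0.64, adjusted p = 0.342), and stood at 13.5 CPM in WT 71 and at 1.82 and 1.93 in the other WT libraries.

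**Figure D4:**
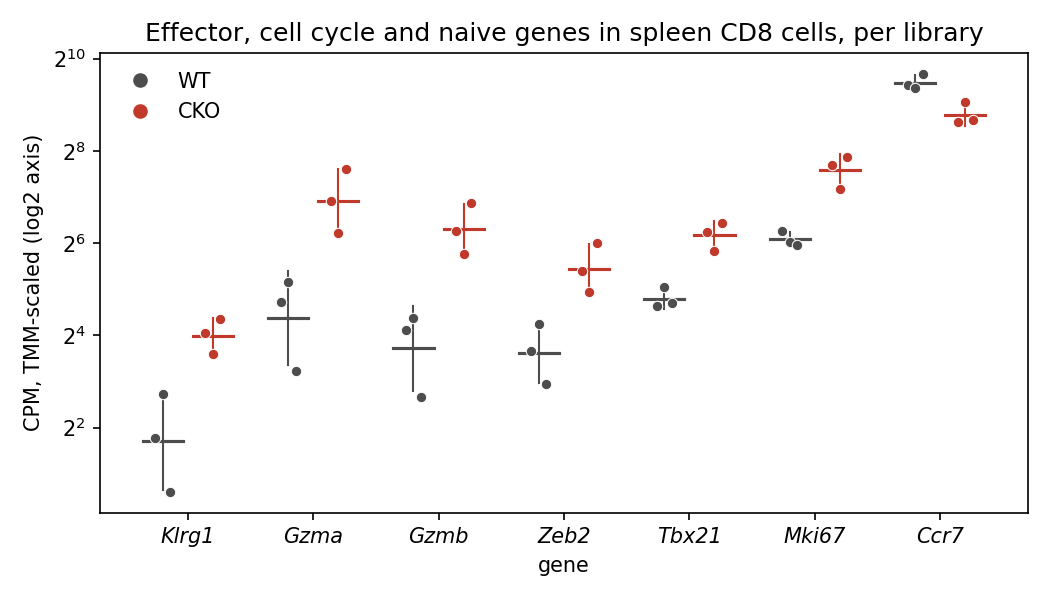
Levels of effector genes, Mki67 and Ccr7 in spleen CD8 cells per library, in CPM on a log2 axis, with WT in grey and CKO in red. Horizontal lines are means of log2 CPM and vertical lines ± 1 SD over 3 libraries; Gzma went from 23.9 ± 13.3 to 129 ± 60.4 CPM and Ccr7 from 719 ± 86.2 to 442 ± 77.6 CPM.

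Many cell cycle genes were higher in spleen CD8 of CKO mice. In this list 28 of the 40 measured members were higher, 0 lower and 12 did not pass; 32 were higher and 1 lower adjusted over the list alone (adjusted p = 1.23e-17 with the preset correlation and adjusted p = 0.146 with an estimated correlation); Mki67, a marker of dividing cells, rose from 68.1 ± 7.57 to 194 ± 45.1 CPM and Top2a from 55.6 ± 3.26 to 135 ± 21.2 CPM. In the inhibitory receptor list 8 of the 17 measured members were higher, 0 lower and 9 did not pass. Ikzf2 stood at 1.12 ± 0.12 and Cd160 at 0.83 ± 0.12, and adjusted over the list alone 8 were higher and 0 lower (adjusted p = 0.00190 with the preset correlation and adjusted p = 0.146 with an estimated correlation). In the p53 target list 7 of the 25 measured members were higher, 1 lower and 17 did not pass. Phlda3 stood at 2.91 ± 0.36 and Bax at 0.64 ± 0.10, and adjusted over the list alone 9 were higher and 2 lower (adjusted p = 0.00265 with the preset correlation and adjusted p = 0.2004 with an estimated correlation). For apoptosis regulators 6 of the 26 measured members were higher, 0 lower and 20 did not pass. Fasl stood at 1.52 ± 0.16 and Apaf1 at 0.54 ± 0.08, and adjusted over the list alone 8 were higher and 0 lower (adjusted p = 0.00995 with the preset correlation and adjusted p = 0.146 with an estimated correlation). In the regulatory and helper list 7 of the 15 measured members were higher, 0 lower and 8 did not pass. Pdcd1 stood at 1.70 ± 0.26 and Capg at 0.78 ± 0.13, and adjusted over the list alone 8 were higher and 0 lower (adjusted p = 0.00212 with the preset correlation and adjusted p = 0.146 with an estimated correlation). In the innate-like list 3 of the 13 measured members were higher, 0 lower and 10 did not pass. Klrb1c stood at 1.41 ± 0.27 and Plac8 at 0.42 ± 0.10, and adjusted over the list alone 6 were higher and 1 lower (adjusted p = 0.0263 with the preset correlation and adjusted p = 0.146 with an estimated correlation). Trdc of the same list was called higher as well (log2 3.24, adjusted p = 0.0151), with an estimate of 4.77 without WT 70. The Trdc call was lost without WT 67, WT 71 or CKO 72.

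Some genes of sterol synthesis and ribosome biogenesis were lower in spleen CD8. For cholesterol biosynthesis 0 of the 20 measured members were higher, 7 lower and 13 did not pass; 0 were higher and 8 lower adjusted over the list alone (adjusted p = 1.83e-05 with the preset correlation and adjusted p = 0.146 with an estimated correlation), with Srebf2, the regulator of sterol synthesis, at -0.52 ± 0.08 and Sqle at -0.82 ± 0.16. In the ribosome biogenesis list 0 of the 26 measured members were higher, 11 lower and 15 did not pass. Npm1 stood at -0.44 ± 0.08 and Pes1 at -0.32 ± 0.07, and adjusted over the list alone 0 were higher and 11 lower (adjusted p = 2.13e-05 with the preset correlation and adjusted p = 0.146 with an estimated correlation). In the arginine methyltransferase list 0 of the 11 measured members were higher, 3 lower and 8 did not pass. Prmt3 stood at -0.46 ± 0.09 and Prmt7 at -0.35 ± 0.10, and adjusted over the list alone 0 were higher and 3 lower (adjusted p = 0.0140 with the preset correlation and adjusted p = 0.146 with an estimated correlation). The third lower member was Prmt5, so part of this list's decrease was set by the design. Among immediate early and heat shock genes 0 of the 17 measured members were higher, 3 lower and 14 did not pass. Junb stood at -0.53 ± 0.07, and adjusted over the list alone 0 were higher and 4 lower (adjusted p = 0.00377 with the preset correlation and adjusted p = 0.406 with an estimated correlation). Some myeloid markers were higher beside these changes; 7 of the 14 measured members were higher, 0 lower and 7 did not pass. Itgax stood at 2.16 ± 0.24 and Itgam at 1.87 ± 0.27, genes that effector CD8 cells can also express, and adjusted over the list alone 9 were higher and 0 lower (adjusted p = 2.13e-05 with the preset correlation and adjusted p = 0.240 with an estimated correlation). Among natural killer markers 7 of the 14 measured members were higher, 0 lower and 7 did not pass. Klra3 stood at 0.98 ± 0.21 and Gzma, shared with the effector list, at 2.44 ± 0.42, and adjusted over the list alone 9 were higher and 1 lower (adjusted p = 6.66e-04 with the preset correlation and adjusted p = 0.2004 with an estimated correlation).

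Among named genes of at least 5 CPM in the higher group, the largest increases in spleen CD8 were those of the long non-coding RNA Miat (log2 3.08 ± 0.29, adjusted p = 1.43e-04), Tcrg-C2 (log2 3.01 ± 0.18, adjusted p = 1.55e-05) and the p53 target Phlda3 given above. Next came the integrin gene Itga1 (log2 2.75 ± 0.18, adjusted p = 2.03e-05), Tcrg (2.75 ± 0.17), the receptor kinase Ret (2.70 ± 0.36) and Klf12 (2.62 ± 0.45, or 3.35 without WT 70). Tcrg-C2 and Tcrg are overlapping annotations of the gamma chain locus, and their counts are uncertain. The largest decreases were those of Tbc1d30 (log2 -1.72 ± 0.17, adjusted p = 1.50e-04) and Tpm3-rs7 (-1.70 ± 0.08), a retrocopy that can share reads with its parent gene. Then followed Ramp3 (-1.48 ± 0.26), Osbpl6 (-1.37 ± 0.36), Ntrk3 (-1.37 ± 0.25), Ptk2 (-1.33 ± 0.16), Igf1r (-1.24 ± 0.19) and Prss12 (-1.15 ± 0.17). Of 13917 genes tested 1368 were higher and 866 lower, 470 and 73 of them by at least 2-fold. Without WT 67 the counts were 844 higher and 488 lower and without WT 71 they were 853 and 462. Without WT 70 and without CKO 72 the lower count was 472 and 531. The Prmt7 call was lost in 5 of the 6 fits that left out 1 library, all but the one without CKO 65. Osbpl6 lost its call without WT 67 or WT 71, and Plac8 without WT 70 or CKO 72 and in the fit over all 12 libraries of the table.

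The genotype effects of both spleen populations were then compared directly, to ask which effects are particular to 1 lineage. The difference, CD8 minus CD4, was positive for Il10 (4.32 ± 0.60, adjusted p = 0.00112), for Zbtb16, a factor of innate-like T cells (4.12 ± 0.41, adjusted p = 1.50e-04), and for Itga1 (3.47 ± 0.45, adjusted p = 6.82e-04). Positive as well were Nrbp2 (4.27 ± 0.55, adjusted p = 6.82e-04) and Pak6 (3.48 ± 0.68, adjusted p = 0.0113), and Tbx21 (1.83 ± 0.35, adjusted p = 0.00992). It was negative for Snrnp40, a component of a splicing particle (-3.03 ± 0.64, adjusted p = 0.0188). Negative differences were also found for Lrrc75b (-1.90 ± 0.21, adjusted p = 2.38e-04), Pcsk1 (-1.79 ± 0.37, adjusted p = 0.0164), Cdr2l (-1.59 ± 0.39, adjusted p = 0.0411) and Rcn3 (-1.51 ± 0.18, adjusted p = 3.83e-04). For Il10, Nrbp2, Zbtb16 and Pak6 the larger part was a fall in spleen CD4 (-3.21, -2.85, -2.73 and -2.69 in this fit). Spleen CD8 levels over both genotypes were low for Il10 (0.305 to 1.62 CPM) and Zbtb16 (0.420 to 2.05 CPM). The rise of Klrg1 was not shown to differ (0.36 ± 0.48, adjusted p = 0.862). Of 14958 genes tested 271 differed with a positive and 112 with a negative sign. With the animal as a block (paired libraries of the same mice) the counts were 672 and 411, and 382 of the 383 genes remained. The block added calls for Gzmb (adjusted p 0.00996, against 0.391 without the block), Gzma (0.0301 against 0.664) and Zeb2 (0.00167 against 0.287). It also added Il7r (0.00132 against 0.118), Ccr7 (0.0175 against 0.418) and Tcf7 (0.0414 against 0.263). Without WT 67 the counts were 131 and 34, and without WT 70 they were 158 and 36. Without WT 71 they were 134 and 52, and without CKO 72 they were 154 and 27. The negative count was 175 without CKO 65 and 46 without CKO 68. Cdr2l lost its call in 5 of the 6 fits that left out 1 animal, all but the one without CKO 65. Snrnp40 lost it without WT 70, WT 71, CKO 68 or CKO 72, and Pcsk1 without WT 67, WT 70 or WT 71. Tbx21 lost it without WT 67, WT 71 or CKO 72, and Pak6 without WT 67. The difference of Snrnp40 was -2.20 without WT 70, and that of Nrbp2 3.67 without WT 71.

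Calls were shared between the spleen populations. Of genes tested in both, 601 were higher in both where independent lists would share 115, and 234 lower in both where they would share 47.2 (Fisher's exact test, two-sided, adjusted p = 1.69e-105 for the lower genes). Of 894 genes called in both populations 835 changed in the same direction and 59 in opposite directions. The same mice gave both populations, so mouse-to-mouse variation is common to both lists. Across tables, thymus CD8 SP and spleen CD8 shared 4 lower genes, where independent lists would share 0.766 (Fisher's exact test, adjusted p = 0.0216). Thymus DP and thymus CD8 SP shared 1 higher gene, Mbnl1, and 1 lower gene, Prmt5 (adjusted p = 0.00497 and 0.00559 by the same test). Prmt5, set by the design, was called lower in each of these populations.

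For thymus CD4 SP against thymus DP the direct comparison of genotype effects called 0 of 12216 genes with edgeR, with 263 at an unadjusted p under 0.05, and 0 with the animal as a block, with 166. Among the genes named in every comparison the adjusted p of the difference ran from 0.983 to 0.986, for example for Ccr7 (0.23 ± 0.43, adjusted p = 0.983). In simulated data for this contrast 2% of genes with a log2 difference of 1 and 58% of those with 2 were recovered. Most smaller differences would be missed in such data, which had the same limit as those for thymus CD4 SP.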

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

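The tests of a scaling of the libraries, of natural killer cells and of the share of effector cells were chosen after the result was seen; the others here were set beforehand.

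Genotype effects differed between spleen CD8 and spleen CD4 for 383 genes by an interaction test. For Il10, Nrbp2, Zbtb16 and Pak6 the larger part of the difference was a fall in spleen CD4. The log2 difference, CD8 minus CD4, was 4.32 for Il10, 4.27 for Nrbp2, 4.12 for Zbtb16, 3.48 for Pak6, 3.47 for Itga1 and 1.83 for Tbx21. It was -3.03 for Snrnp40, -1.90 for Lrrc75b, -1.79 for Pcsk1, -1.59 for Cdr2l and -1.51 for Rcn3. Of the 10 splits of the 6 animals into 3 and 3, 1 called as many genes, the real one, and the highest of the others called 0; 10 splits are too few for a share under 0.05.

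In other pairs of populations some genes had estimates of opposite sign without overlap of the genotypes, and these differences were not tested. Of the values below, only those of Gzmb and Tcf7 in spleen CD8 passed the test of their own population. Gzmb was at -5.45 in thymus CD4 SP and 2.48 in spleen CD8. Prf1 was at 0.26 in thymus DP and 0.17 in spleen CD4, against -0.40 in thymus CD8 SP. Tcf7 was at 0.0874 in thymus CD8 SP and -0.38 in spleen CD8, and Il2rg at -0.11 in thymus CD8 SP and 0.18 in spleen CD4.

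Effector genes were higher in spleen CD8 of CKO mice, with 35 of 38 list members called. A scaling of the libraries is argued against by the mean of the list minus the median of all tested genes. A factor per library cancels in this value. It was 1.45 log2 units higher in CKO, with an SE of 0.256 (WT 0.130 ± 0.290, CKO 1.58 ± 0.335, SD, n = 3). The value comes from the same counts as the calls, so it is no separate evidence of the rise. Natural killer cells in the sort may contribute: the 13 killer cell markers outside the effector list went from 112 ± 2.20 to 148 ± 23.5 summed CPM (SD, n = 3), a rise of 0.0118 times that of the effector list (3184 ± 198 to 6292 ± 946), and the upper end of that ratio over 2 standard errors, 0.0205, passes the bound of 0.02 set for excluding them. A larger share of effector cells and a change within each cell cannot be told apart in bulk libraries; the naive list had a mean log2 fold change of -0.14 with an SE of 0.07 over its members. A change of gene expression with the loss of Prmt5 stays open as a hypothesis.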

How the results depend on the processing

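Settings added after seeing the data were sex as a covariate, male libraries alone, leaving out CKO 14 with CKO 17, the DP list as a covariate and a GC correction. In thymus DP, DESeq2 called 6 genes higher and 8 lower, no filter 2 lower, the fit over 12 libraries 0 and 0 (Prmt5 at -1.09, adjusted p = 1), and leaving out 1 library gave 0 to 7 higher and 1 to 38 lower. In thymus CD4 SP DESeq2 called 1 gene lower; every other setting run called 0. In thymus CD8 SP, DESeq2 called 79 higher and 126 lower, no filter 180 and 270, the strict filter 3 higher, sex as a covariate 2 and 1, male libraries alone 4 lower, and leaving out 1 library 1 to 11 higher and 0 to 40 lower. Prmt5 there stayed between -0.36 and -0.29 without 1 library and lost its call, as it did with the strict filter (-0.31, adjusted p = 0.0543), the replicate block (-0.31, adjusted p = 0.0674), sex (-0.31, adjusted p = 0.356) and male libraries alone (-0.30, adjusted p = 0.570); the last 2 leave fewer degrees of freedom, and among male libraries the CKO arm is the 1 library CKO 1. With the replicate block 10 of the 13 called genes named in thymus CD8 SP besides Prmt5 were kept, and Kifc1, Mbnl1 and Ifi203 lost the call, while Ccr7 gained it (adjusted p = 0.0421). Apart from these and the spleen contrast, the block changed no call of a named gene.

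Leaving out 1 library gave 706 to 1232 genes higher and 379 to 912 lower in spleen CD4, and 844 to 1320 and 462 to 978 in spleen CD8. The spleen contrast had 672 positive and 411 negative genes with the animal as a block, 574 and 270 with no filter, and 131 to 381 and 27 to 175 without 1 animal; the thymus contrast had 0 to 1 negative gene. With at least 2-fold changes, a stricter definition, the spleen populations shared 77 higher and 8 lower genes. Lists called fell to 0 in all 5 comparisons with an estimated correlation and, with fry, to 0 in each thymus comparison and 4 in spleen CD4; no filter gave 8 lists in thymus DP and 11 in spleen CD4, and leaving out 1 library 4 to 8 in thymus DP and 4 to 10 in thymus CD4 SP. With DESeq2 size factors every called gene named in thymus DP, thymus CD8 SP and both spleen populations kept its call.

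Signs that turned belonged to values without a call, except for 2 lists. Without 1 library Cd4 ran from -0.0344 (without CKO 23) to 0.0480 in thymus DP, with -0.0134 without WT 18. In thymus CD4 SP it ran from -0.0226 (without CKO 14) to 0.392, with -0.0312 without CKO 14 and CKO 17. In spleen CD8 it ran from -1.41 to 0.63 (without WT 71). Cd8a in thymus CD4 SP ran from -1.37 to 0.40 (without CKO 17), with 0.70 for the DP list as a covariate and 0.0197 for the GC correction. In thymus CD8 SP it ran from -0.0483 (without CKO 2) to 0.0785, with -0.00225 without WT 1, -0.0290 with sex and -0.0245 with male libraries alone. Gzma there ran from -0.0255 (without WT 2) to 0.168, with -0.0241 without WT 3 and -0.0161 without CKO 1. Cdkn1a in spleen CD4 ran from -0.15 (without CKO 72) to 0.489, with -0.0595 without WT 67. Il7r in spleen CD8 ran from -0.0185 (without WT 67) to 0.0860, with -0.0105 without CKO 72. Prf1 in the spleen contrast ran from -0.0219 (without CKO 72) to 0.256. The interferon and cell cycle lists of thymus CD4 SP turned without CKO 17 (adjusted p = 0.350 and 0.524), and had 5.19e-13 and 1.35e-22 without CKO 14. Where the setting itself does not remove libraries or genes, the cause was not tested.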

Other observations

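Of the tests below, those of a Cd4-driven transgene and of Prmt5 loss acting alike, and all 4 tests of the library CKO 14, were chosen after values of the same genes or library had been seen. Some T cell receptor signalling genes changed in both spleen populations. Lck, the kinase bound to the coreceptors, rose in spleen CD4 from 412 ± 28.4 to 736 ± 48.5 CPM (log2 0.84 ± 0.07, adjusted p = 2.93e-05) and in spleen CD8 from 431 ± 39.5 to 735 ± 26.8 CPM (log2 0.78 ± 0.08, adjusted p = 1.52e-04), and Ptprc (CD45) rose in both (log2 0.54 ± 0.07, adjusted p = 3.87e-04; log2 0.57 ± 0.06, adjusted p = 1.68e-04). For this list in spleen CD4 4 of the 25 measured members were higher, 5 lower and 16 did not pass; 6 were higher and 6 lower adjusted over the list alone (adjusted p = 0.652 with the preset correlation and adjusted p = 0.745 with an estimated correlation). In spleen CD8 5 of the 25 measured members were higher, 2 lower and 18 did not pass; 6 were higher and 3 lower adjusted over the list alone (adjusted p = 0.386 with the preset correlation and adjusted p = 0.406 with an estimated correlation), and fry called it with a positive direction (adjusted p = 0.0122). Core splicing genes, substrates or partners of the methylosome among them, had 7 of 35 members higher and 0 lower in spleen CD4 (adjusted p = 0.0520 with the preset correlation and adjusted p = 0.552 with an estimated correlation) and 5 of 35 in spleen CD8 (adjusted p = 0.477 with the preset correlation and adjusted p = 0.710 with an estimated correlation). Snrnp200 rose in both (log2 0.64 ± 0.08, adjusted p = 3.05e-04; log2 0.52 ± 0.07, adjusted p = 8.73e-04), as did Prpf8 (0.44 ± 0.08 and 0.41 ± 0.07).

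A few interferon genes changed in both spleen populations. Usp18, a brake on interferon receptors, rose in spleen CD4 (log2 1.42 ± 0.22, adjusted p = 0.00126) and spleen CD8 (log2 1.14 ± 0.20, adjusted p = 0.00318), while Irf9, an interferon regulatory factor, fell (log2 -0.40 ± 0.09, adjusted p = 0.00963; log2 -0.46 ± 0.09, adjusted p = 0.00592). In spleen CD4 3 of the 35 measured members were higher, 2 lower and 30 did not pass; 3 were higher and 2 lower adjusted over the list alone (adjusted p = 0.652 with the preset correlation and adjusted p = 0.892 with an estimated correlation). In spleen CD8 5 of the 35 measured members were higher, 2 lower and 28 did not pass; 5 were higher and 2 lower adjusted over the list alone (adjusted p = 0.440 with the preset correlation and adjusted p = 0.852 with an estimated correlation). Of the innate-like list Zbtb16, from 17.1 ± 1.40 to 2.57 ± 0.142 CPM (log2 -2.73 ± 0.16, adjusted p = 1.67e-06), Icos (-0.71 ± 0.09) and Il4 (-3.21 ± 0.73) fell in spleen CD4. Il4, also a member of the regulatory and helper list, was low, at 0.521 ± 0.0949 CPM in WT and 0.0511 ± 0.0445 CPM in CKO. For the innate-like list 1 of the 15 measured members were higher, 4 lower and 10 did not pass; 2 were higher and 5 lower adjusted over the list alone (adjusted p = 0.189 with the preset correlation and adjusted p = 0.730 with an estimated correlation). The share of counts from mitochondrial genes was lower in CKO spleens, 1.36 to 1.38% against 1.52 to 1.75% in CD4 and 1.41 to 1.51% against 1.76 to 1.89% in CD8.

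Transcripts of 2 unnamed gene models on chromosome 3, chosen after their values were seen, were present almost only in CKO libraries. Gm33707, annotated as a processed pseudogene (60769887 to 60770455, GRCm38), had 4178 counts in spleen CD4 of CKO mice and 1 in WT, a depth-scaled ratio of 4255 (95% counting interval 763 to 168090), and went from 0.0101 to 2.31 CPM in thymus CD8 SP (log2 7.35 ± 0.59). Gm37035 (61001639 to 61003786), antisense to P2ry1, had 873 counts against 1 in spleen CD4, and Mbnl1 (60472830 to 60629750), called higher in thymus DP and thymus CD8 SP, lies within 1 Mb of both but was at 0.05 ± 0.07 in spleen CD4, where they were highest. Reads shared with near-identical transcripts are argued against: 18.4% and 45.4% of their 31-base words occur in other genes, and 0 of the 5 tested among those 10 genes were higher in spleen CD4 CKO at an edgeR adjusted p under 0.05, with P2ry1 at 0.26 ± 0.57, while Gm8483, untested and sharing the most words with Gm33707, had 2 counts in CKO and 2 further genes had 0 (the last 2 are not in the table). In spleen CD8 the ratio of CKO to WT was 1.54 (3 counts against 2, interval 0.177 to 18.5), which lies below the spleen CD4 interval and argues against a loss of Prmt5 acting alike in both; a Cd4-driven transgene inserted nearby may account for it, with CKO levels 1400 times higher in spleen CD4 than in spleen CD8 (interval 479 to 6793), but that ratio had been seen before the test, and transgene and knockout cannot be told apart without a library that carries the transgene alone.

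The library thymus CD4 SP CKO 14 stood apart, at a root mean square log2 distance of 1.15 from the mean of the other 5 libraries, 1.56 times the next, CKO 17 at 0.741. A sort with more DP cells is argued against as the whole cause, since genes that differ little between WT DP and WT CD4 SP deviated 0.862 times as much as genes that do; as part of the cause it stays open, since the slope of its deviation on that difference, 0.233, was the highest of the 6 (next 0.191 in WT 24), with Cd8a and Rag1 above WT, while its DP list had a mean log2 CPM of 7.24 against 7.18 to 7.57 in WT. A DP library under a CD4 SP label is argued against by its mature single-positive list, with a mean log2 CPM of 6.96 against 4.39 to 4.88 in the 6 DP libraries. GC content bias may account for part: its deviation correlated with GC across genes (r = 0.54; genes are not independent replicates), and a correction lowered the distance to 0.910, 1.26 times the next library, within the bound of 1.5 that was set. That bound lay close to the starting ratio of 1.56 and CKO 14 remained the farthest of the 6, so the GC explanation stays open, and no biological explanation was tested.

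Other splits of the libraries were refitted in every comparison, 10 each with the real one, too few for a share under 0.05. In thymus DP the real split called 3 genes and the highest other 1; in thymus CD4 SP all 10 splits called 0; in thymus CD8 SP the real split called 17 and the highest other 6, the one that sets WT 1, CKO 1 and CKO 3 against the rest. The real split called 2024 genes in spleen CD4, with 0 as the highest other, and 2234 in spleen CD8, with 1. For the thymus contrast all 10 splits called 0.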
